A study of Mus musculus with 8 samples.

How the data were processed

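Bulk RNA sequencing was done on quadriceps muscle of 8 wild-type male C57BL/6 mice, 1 library per mouse. The design text gives 4 mice that received MC38 cells, a mouse colorectal cancer line, under the skin (scMC38) and 4 that received the same volume of saline (control). Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by the library names in the sample descriptions. Mice were 8 weeks old and muscle was taken at day 28, per the labels.

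Total RNA was isolated with a column kit (RNeasy Mini) and libraries were made with the Universal Plus mRNA-seq kit (Nugen/Tecan), per the labels' protocols. The submitters' processing notes name fastp 1.0.1, FastQC 0.12.1, MultiQC 1.30, Salmon 1.10.3 and R 4.4.3 and the mouse build GRCm39, with no roles or order. The annotation release and the way transcripts were summed to genes are not given in the sources used here. The deposited table holds estimated counts per gene, not scaled for depth or gene length, and 49.3% of its nonzero values carry a fraction. Because Salmon divides reads among similar transcripts by a model, values of near-identical genes are uncertain: this concerns Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt, Csf2rb with Csf2rb2, and mitochondrially encoded genes with their nuclear copies. Strand handling is not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart. Gene symbols are those of the table. The annotation at hand belongs to an earlier mouse build, so no coordinates are given.

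The table has 35667 rows. Of these, 144 have no symbol and were left out. They held between 0.00270% and 0.00403% of each library's counts. The rows of 26 symbols that occur more than once were summed, which gave 35494 symbols, and the estimated counts were rounded to whole numbers. Total counts per library ran from 50.5 to 62.1 M. At these totals counting error is small for genes above a few counts per M (CPM), and the spread between mice sets the precision: the common biological coefficient of variation was 27.3%. Within each group, all 6 pairs of libraries differed far beyond counting noise, with a chi-square per degree of freedom between 63.2 and 480 over genes with at least 10 counts in the pair, so each library was counted as 1 replicate.

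Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10, minimum total 15), TMM scaling, and the robust quasi-likelihood F test of scMC38 minus control with no covariate. This left 14112 genes. P-values were adjusted by Benjamini-Hochberg over these genes, and 0.05 was the threshold for a call. A standard error of a log2 fold change is the one implied by the F statistic. CPM values are TMM-scaled, and log2 CPM values carry a prior count of 2. Unless another test is named, adjusted p-values of genes come from edgeR. Shares of counts and principal component scores were compared between groups with two-sided exact permutation tests over the 70 assignments of 8 libraries, for which 0.0286 is the smallest possible p, with Benjamini-Hochberg adjustment over the 6 measures.

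Before the data were examined, 41 gene lists of 10 to 93 genes were written down, covering muscle wasting, proteolysis, signalling, inflammation, metabolism, fibre types, matrix and the cell types a muscle sample could hold. Of the 1000 genes listed, 38 stand on more than 1 list. The 39 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Camera asks whether a list's genes differ more than the other genes do. No list call was held when the correlation between genes was estimated from the 8 libraries, so that adjusted p is printed for each called list. Fry, which asks whether a list's genes move on balance in a single direction, was run beside it. Counts of called members are given over all genes and, where stated, adjusted over the list alone. The level of a list in a library is the mean log2 CPM of its tested members relative to the control mean.

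The genes named were set by a rule written before the data were examined. The first part takes called genes with a mean log2 CPM of at least 1, a proper symbol and all 4 scMC38 libraries on the same side of all 4 controls, and keeps the 12 with the largest rise and the 12 with the largest fall. The second takes up to 4 called members of each list or, where none was called, up to 2 with the smallest p, given as values. The third is a set of 15 genes reported whatever their values: Fbxo32, Trim63, Fbxo30, Fkbp5, Cdkn1a, Mstn, Pdk4, Socs3, Lcn2, Serpina3n, Ppargc1a, Myh1, Myh2, Myh4 and Myh7. Some genes that the rule selects are not reported here. Osmr, Loxl2, Col1a1, Sele, Ackr1, Plvap, Hba-a1, Hba-a2, Hbb-bs and Alas2 were chosen after their values were seen. The bone, marrow and platelet lists of the closing section were written after the patterns they test had been seen but before the values of their genes were, apart from 2 marrow genes that stand on the fixed lists. Ibsp and Mpo were picked from them as examples after their values were seen.

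On simulated counts with the means, depths and dispersion of these libraries and 200 changed genes among 14112, edgeR recovered 11.9% of the 67 genes changed 1.5-fold, 60.6% of the 66 changed 2-fold and 83.6% of the 67 changed 4-fold, with 1 false call among 105 calls. DESeq2 1.42.0 made 41 false calls among 178 on the same counts. The alternatives tried were DESeq2 size factors in edgeR, total-count scaling, scaling without mitochondrially encoded genes, DESeq2's Wald test, limma-voom with and without quality weights, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, an adjusted p under 0.10, the replicate number as a block, and each library left out in turn. Leaving out scMC38 1 and 3 together, and control 1 and 2 together, was chosen after seeing the data.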

Results

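Quadriceps transcriptomes were measured at day 28 in 4 mice carrying subcutaneous MC38 colorectal tumours and 4 mice injected with saline. The design implies a single comparison, which asks how muscle gene expression differs between mice with and without this tumour. The series title describes the wasting in this model as mild. Total counts per library were alike, at 56.8 ± 5.20 M in controls and 55.9 ± 4.10 M in scMC38 (SD, n = 4).

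Muscle samples of tumour-bearing mice showed higher mRNA of the ubiquitin ligase genes Fbxo32 and Trim63 and the inflammatory genes Lrg1, Il6ra and Il4ra. The haemoglobin genes, which are red cell genes, and the adhesion gene Selp were also higher. The collagen genes Col3a1, Col5a3, Col6a1 and Col6a2 were lower. The libraries scMC38 1 and 3 also held mRNA of bone cells and marrow progenitors, such as Ibsp and Mpo. At an adjusted p under 0.05, 104 genes were higher and 66 lower in scMC38, out of 14112 tested. In all 170, the 4 scMC38 libraries lay on the same side of the 4 controls. Over all tested genes 1873 (13.3%) were separated in this way, where chance gives 2.86% on average over all assignments of the libraries. As genes vary together, a single assignment can lie far from that average, and the share in the other splits was not counted. The change exceeded 2-fold for 53 of the higher and 31 of the lower genes.

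The libraries were not evenly spread. The first principal component held 52.7% of the variance and set scMC38 3 (score 61.2) and scMC38 1 (29.0) apart from the other 6 libraries, which lay between -23.9 and -7.62. Its group difference reached the smallest p the design allows (exact permutation p = 0.0286, adjusted p = 0.0858). Control 1 and control 2 held more mitochondrially encoded counts (24.3% and 29.7%) than the other 6 libraries (14.4% to 18.9%). The mean share was higher in controls, but a group difference was not detected (21.8% ± 6.44 against 16.7% ± 2.05, SD, n = 4, exact permutation p = 0.257). Without scMC38 1 and 3, edgeR called 25 genes higher and 39 lower, 40 of them shared with the 170. Without control 1 and 2 it called 0, with 1605 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.138.

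**Figure D1:**
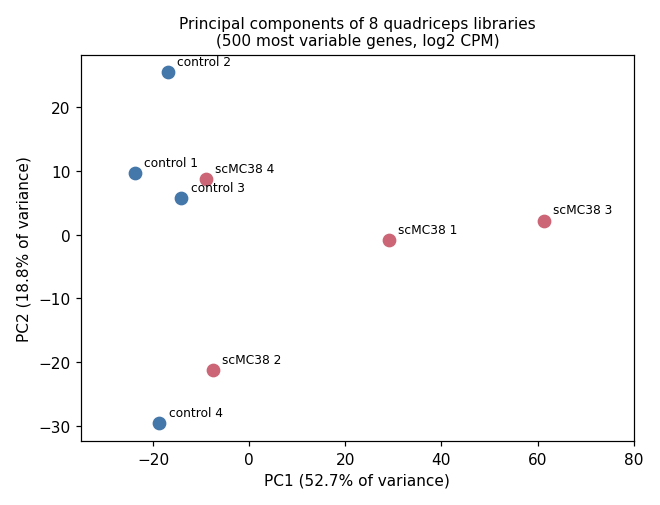
Scores of the 8 libraries on the first (x axis, 52.7% of variance) and second (y axis, 18.8%) principal components of the 500 most variable genes, 1 point per library, blue for control and red for scMC38. The libraries scMC38 3 and scMC38 1 lie far to the right, at 61.2 and 29.0, and control 2 and control 4 mark the ends of the second axis, at 25.5 and -29.6.

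The number of calls depended on each single library. Higher and lower calls by edgeR were 1 and 1 without control 1, 16 and 9 without control 2, 11 and 10 without control 3, and 47 and 52 without control 4. They were 24 and 26 without scMC38 1, 25 and 14 without scMC38 2, 59 and 34 without scMC38 3, and 52 and 14 without scMC38 4. Of the 47 called genes named in the text, Tmem252 and Nrep were called in all 8 of these fits, the other 45 lost the call in at least 1, and all 47 kept their direction. The kept direction could hardly fail, as every called gene had all scMC38 libraries on 1 side of all controls. Scaling by total counts alone shifted the median of all genes by 0.11 on the log2 scale and called 216 higher and 51 lower, so that 80.9% of calls were higher against 61.2% with TMM. Of the 39 gene lists tested, camera called 15 higher and 11 lower with its preset correlation and 0 with an estimated one, and 17 of these 26 were called in all 8 fits that leave out 1 library. Fry called 6 lists higher and 1 lower.

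Both classical muscle ubiquitin ligases rose. Fbxo32, which encodes atrogin-1, went from 420 ± 92.5 to 1449 ± 454 CPM (SD, n = 4), a log2 fold change of 1.79 (SE 0.26, adjusted p = 0.0273). Trim63, which encodes MuRF1, went from 312 ± 87.1 to 915 ± 267 CPM (log2 fold change 1.55, SE 0.25, adjusted p = 0.0322). Eda2r, the ectodysplasin A2 receptor, rose by 1.82 (SE 0.28) and the growth arrest gene Gadd45a by 0.74 (SE 0.12) on the log2 scale. These 4 were the members called among the 24 tested atrophy genes, with 6 higher and 0 lower when adjusted over the list alone. The list as a whole was higher by camera (median log2 fold change 0.31, adjusted p = 1.3e-06; adjusted p = 0.24 with an estimated correlation). Its median was 0.20 without scMC38 1 and 0.12 without control 1 and 2 together. The ligase Fbxo30 (0.04, adjusted p = 0.843), the cell cycle inhibitor Cdkn1a (0.42, adjusted p = 0.531) and the myokine Mstn, myostatin (0.29, adjusted p = 0.624) did not pass. Fbxo32 lost its call without control 1, control 2, control 3 or scMC38 2 (adjusted p = 0.0963, 0.0638, 0.0945 and 0.0734), and Trim63 kept it only without control 3 (adjusted p = 0.0484). Eda2r kept its call only without control 4 and Gadd45a only without scMC38 3, with adjusted p up to 0.107 and 0.115 in the other fits.

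Among 31 proteasome subunits, 29 had a positive log2 fold change and Psma5 was called (0.36, SE 0.07, adjusted p = 0.0480), with 6 higher when adjusted over the list alone. The median was 0.14 (camera adjusted p = 1.2e-05; adjusted p = 0.50 with an estimated correlation), 0.083 without scMC38 4 and 0.24 without scMC38 1 and 3 together. Of 29 autophagy and lysosome genes, 26 were positive and Ulk1, the kinase that starts autophagy, was called (0.55, SE 0.10, adjusted p = 0.0485), with 10 higher when adjusted over the list alone. That list had a median of 0.22 (camera adjusted p = 2.4e-06; adjusted p = 0.078 with an estimated correlation). Psma5 was not called in any fit that leaves out 1 library (adjusted p from 0.0714 to 0.129), and Ulk1 only in the fit without scMC38 3 (up to 0.147 in the others).

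Growth and stress signalling genes were also among the calls. Pik3r1, the regulatory subunit of PI3-kinase (1.03, SE 0.16, adjusted p = 0.0315), and Eif4ebp1, the translation repressor 4E-BP1 (0.96, SE 0.11, adjusted p = 0.0162), rose within the 25 IGF1, insulin and mTOR genes (5 higher and 1 lower when adjusted over the list alone, median 0.21, camera adjusted p = 0.017; adjusted p = 0.43 with an estimated correlation). Its camera call was lost without control 2, scMC38 2 or scMC38 4 (adjusted p = 0.0594, 0.0594 and 0.0600), and without control 1 and 2 together (adjusted p = 0.194). The median was 0.029 without scMC38 1, where the list stayed called (adjusted p = 0.0236), 0.14 without scMC38 2 and 0.11 without scMC38 1 and 3 together. Of 24 glucocorticoid-responsive genes none rose past the threshold and the phosphatase gene Dusp1 fell by 0.90 (SE 0.15, adjusted p = 0.0341), while 6 were higher and 1 lower when adjusted over the list alone. The list's median was 0.24 (camera adjusted p = 0.012; adjusted p = 0.50 with an estimated correlation). Its call was lost without control 1, scMC38 1 or scMC38 4 (adjusted p = 0.0562, 0.0875 and 0.0600), without scMC38 1 and 3 together (median 0.089, adjusted p = 0.287) and without control 1 and 2 together (adjusted p = 0.129). Its median was 0.40 without control 4. Fkbp5, a glucocorticoid receptor target, stood at 0.94 (SE 0.30, adjusted p = 0.136). In the 17 p53 targets, Eda2r and Gadd45a were called and 4 were higher when adjusted over the list alone (median 0.24, camera adjusted p = 0.00076; adjusted p = 0.078 with an estimated correlation), with a median of 0.15 without control 4. In the 22 NRF2 and oxidative stress genes, Gpx3, a secreted glutathione peroxidase, rose by 0.97 (SE 0.18, adjusted p = 0.0481), with 9 higher and 1 lower when adjusted over the list alone (median 0.35, camera adjusted p = 7.6e-05; adjusted p = 0.078 with an estimated correlation). With 1 library left out, Eif4ebp1 lost its call without control 1 (adjusted p = 0.0865). Pik3r1 kept its call only without scMC38 2 or scMC38 3 (up to 0.114 otherwise), Dusp1 only without scMC38 3 (up to 0.107 otherwise), and Gpx3 in none (0.0554 to 0.127).

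Ppp1r15a, which encodes the stress-induced phosphatase subunit GADD34, rose by 0.70 (SE 0.10, adjusted p = 0.0299), and kept its call only without control 4, scMC38 3 or scMC38 4 (up to 0.0963 otherwise). It was the call among 26 integrated stress and unfolded protein response genes, of which 3 were higher and 1 lower when adjusted over the list alone, and the list did not pass (median 0.14, camera adjusted p = 0.096), although it was called higher without scMC38 1 or scMC38 2 (adjusted p = 0.0449 and 0.0461). Of 23 heat shock and chaperone genes, 22 had a negative log2 fold change and none was called, over all genes or over the list alone. Hspb3 (-0.47, adjusted p = 0.0849) and Hspa1b (-2.03, adjusted p = 0.133) had the smallest p. Their list was lower by camera (median -0.21, adjusted p = 0.0038; adjusted p = 0.49 with an estimated correlation), and not without scMC38 3 (adjusted p = 0.0794) or without scMC38 1 and 3 together (median -0.12, adjusted p = 0.583). Its median was -0.13 without control 1 and 2 together. Of 79 cytosolic ribosomal protein genes, 76 were positive and none was called. Rpl10 (0.30, adjusted p = 0.153) and Rpl3 (0.59, adjusted p = 0.159) came closest, and the list had a median of 0.16 (camera adjusted p = 1.5e-06; adjusted p = 0.62 with an estimated correlation), 0.10 without scMC38 3 and 0.075 without scMC38 1 and 3 together.

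**Figure D2:**
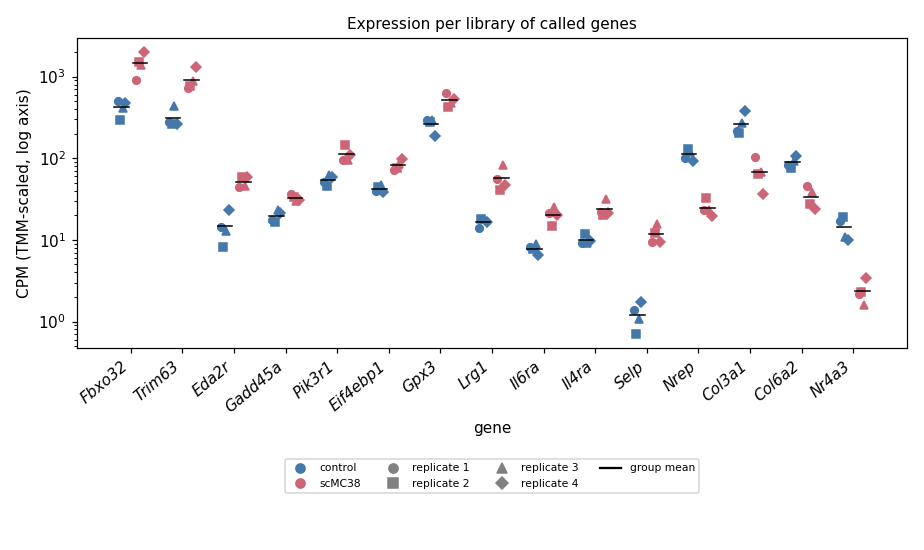
CPM on a log axis (y) of 15 called genes (x), each symbol 1 library, blue for control and red for scMC38, with marker shapes for the replicate number and a black line for each group mean. Red and blue symbols do not overlap for any of the 15 genes. Fbxo32 runs from 293 to 501 CPM in controls and from 906 to 2010 CPM in scMC38.

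An IL-6 and acute phase response was the fixed signalling list with the smallest camera p. Of its 22 tested members 5 were called, all higher: Lrg1, a leucine-rich glycoprotein induced by inflammation (1.76, SE 0.22, adjusted p = 0.0167), Bcl3, an atypical IkB protein (1.74, SE 0.30, adjusted p = 0.0383), and the receptor genes Il6ra (1.38, SE 0.16, adjusted p = 0.0162), Il4ra (1.27, SE 0.16, adjusted p = 0.0201) and Osmr (0.90, SE 0.12, adjusted p = 0.0241). Lrg1 went from 16.8 ± 1.86 to 56.9 ± 18.9 CPM (SD, n = 4). Adjusted over the list alone, 12 were higher and 0 lower. The list's median was 1.26 (camera adjusted p = 8.3e-15; adjusted p = 0.078 with an estimated correlation). Its median was 0.82 without scMC38 1, 0.56 without scMC38 1 and 3 together and 0.83 without control 1 and 2 together. Its level was higher in scMC38 1 and 3 (1.31 and 1.53) than in scMC38 2 and 4 (0.64 and 0.51). Socs3, the feedback inhibitor of this pathway (1.45, SE 0.37, adjusted p = 0.0909), Lcn2 (6.28, SE 1.65, adjusted p = 0.0973) and Serpina3n (1.40, SE 0.69, adjusted p = 0.281) did not pass. Lcn2, a neutrophil granule and acute phase gene, stood at 32.7 and 283 CPM in scMC38 1 and 3, at 1.72 and 4.67 CPM in scMC38 2 and 4, and at 0.437 to 1.64 CPM in controls. Calls were lost without control 1 or 2 for Il6ra (adjusted p up to 0.0865), without control 1 or 3 for Il4ra (up to 0.0894), without control 1, 2 or 3 for Lrg1 (up to 0.0865), and without these or scMC38 1 for Osmr (up to 0.0963). Bcl3 kept its call only without scMC38 3 or scMC38 4 (up to 0.129 otherwise).

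Bcl3 was the call among 19 NF-kB and TNF targets, with 2 higher when adjusted over the list alone (median 0.23, camera adjusted p = 0.0083; adjusted p = 0.50 with an estimated correlation). That list did not pass without control 3 (adjusted p = 0.0629) or without scMC38 1 and 3 together (median 0.090, adjusted p = 0.437). Its median was 0.39 without control 4 and 0.11 without scMC38 3. Interferon-stimulated genes did not pass as a list of 47 (median 0.0065, mean -0.07, camera direction down, adjusted p = 0.19). None was called over all genes and 1 was lower when adjusted over the list alone. The chemokine gene Cxcl9 (-2.09, adjusted p = 0.0510) and the GTPase gene Iigp1 (-0.82, adjusted p = 0.110) had the smallest p. The list was called lower without control 1 (adjusted p = 0.0167), without scMC38 3 (median -0.17, adjusted p = 0.00736) and without scMC38 1 and 3 together (median -0.23, adjusted p = 0.00141).

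Markers of white blood cells were high in scMC38 1 and 3. These libraries also held mRNA of bone cells (Ibsp at 40.6 and 137 CPM) and marrow progenitors (Mpo at 18.3 and 174 CPM). The white blood cell and cell cycle levels in them therefore cannot be assigned to muscle. The neutrophil list stood 5.44 and 8.45 above the control mean on the log2 scale in scMC38 1 and 3, and 1.1 and 2.40 above it in scMC38 2 and 4, while controls spread from -0.92 to 1.14. Of its 12 tested members none was called over all genes and 11 were higher when adjusted over the list alone (median 7.09, camera adjusted p = 4.2e-07; adjusted p = 0.49 with an estimated correlation). The median was 4.35 without scMC38 3 and 1.51 without scMC38 1 and 3 together, where camera still called the list (adjusted p = 1.45e-06). Retnlg (7.54, SE 1.80, adjusted p = 0.0849) and the G-CSF receptor gene Csf3r (3.49, SE 0.86, adjusted p = 0.0865) came closest. Macrophage markers had 0 of 20 called and 10 higher when adjusted over the list alone (median 1.13, camera adjusted p = 1.3e-06; adjusted p = 0.49 with an estimated correlation), with Ccr2 at 1.76 (adjusted p = 0.0713) and Tyrobp at 2.05 (adjusted p = 0.0920). Their level was 1.59 and 1.97 in scMC38 1 and 3 and 0.49 and -0.21 in scMC38 2 and 4, and the call was lost without scMC38 1 and 3 (median 0.17, adjusted p = 0.153).

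B and plasma cell markers (0 of 11 called, 4 higher when adjusted over the list alone, median 0.89, camera adjusted p = 0.020; adjusted p = 0.53 with an estimated correlation) were led by Jchain (3.06, adjusted p = 0.116) and Cd74 (0.89, adjusted p = 0.124). Their call was lost without control 1, control 4, scMC38 1 or scMC38 3 (adjusted p = 0.0695, 0.0659, 0.0646 and 0.199), without scMC38 1 and 3 together (median -0.06, adjusted p = 0.923) and without control 1 and 2 together (adjusted p = 0.116). The median without scMC38 3 was 0.48. The list was not called with total counts (adjusted p = 0.0877) or the filter of at least 1 CPM (adjusted p = 0.228). Cell cycle genes followed the same 2 libraries, with a level of 1.84 and 3.16 in scMC38 1 and 3 against 0.07 and -0.24 in scMC38 2 and 4. None of 23 was called over all genes and 10 were higher when adjusted over the list alone (median 2.05, camera adjusted p = 2.4e-06; adjusted p = 0.50 with an estimated correlation). The median of the cell cycle list was 0.58 without scMC38 3 and -0.01 without scMC38 1 and 3 together (adjusted p = 0.923). With the filter of at least 1 CPM it was 0.80. Mki67 stood at 4.69 (adjusted p = 0.126) and Mcm7 at 0.75 (adjusted p = 0.126). T and NK cell markers, of which 3 were tested (median 0.50), and epithelial markers, also 3 (median -1.51), were too few for a list test. None of them was called over all genes. The T cell genes Il7r (1.00, adjusted p = 0.441) and Cd4 (0.50, adjusted p = 0.637) and the epithelial keratin gene Krt19 (-1.71, adjusted p = 0.133) and Cdh1, E-cadherin (-1.51, adjusted p = 0.308), were below 1 CPM in both groups, with 0 T and NK cell markers passing and 1 epithelial marker lower when adjusted over each list alone.

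The level of the erythroid list was above every control (-0.25 to 0.51) in all 4 scMC38 libraries, from 1.3 in scMC38 2 to 2.76 in scMC38 3. Of 10 tested members 8 were called, all higher, and 9 were higher when adjusted over the list alone (median 1.71, camera adjusted p = 9e-16; adjusted p = 0.078 with an estimated correlation). The haemoglobin genes Hba-a1 (1.74, SE 0.32), Hba-a2 (1.67, SE 0.31), Hbb-bs (1.56, SE 0.28) and Hbb-bt (1.91, SE 0.30) rose, as did Alas2, the erythroid enzyme of haem synthesis (1.59, SE 0.25), with adjusted p between 0.0315 and 0.0467. Haemoglobin genes took 0.0652% ± 0.0217 of counts in controls and 0.227% ± 0.0808 in scMC38 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0858). The red cell membrane gene Slc4a1, which encodes band 3, rose by 4.94 (SE 0.92, adjusted p = 0.0479). It stood at 27.1 and 32.3 CPM in scMC38 1 and 3 and at 2.71 and 4.31 CPM in scMC38 2 and 4, against 0.234 to 0.980 CPM in controls. Without scMC38 1 and 3, Slc4a1 (2.71, adjusted p = 0.0657) and Hbb-bt (1.51, adjusted p = 0.0775) were not called. With 1 library left out, Slc4a1 was called only without scMC38 2 (adjusted p up to 0.157 otherwise). Hbb-bs, Hbb-bt and Alas2 were called only without control 2 (up to 0.145, 0.113 and 0.114 otherwise), and Hba-a1 and Hba-a2 in no such fit (up to 0.154 and 0.157).

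Other large rises were outside the blood lists. Selp, P-selectin, the adhesion molecule by which venules capture leukocytes, went from 1.22 ± 0.439 to 11.6 ± 2.94 CPM (SD, n = 4; log2 fold change 3.26, SE 0.30, adjusted p = 0.00731). Tmem252, a transmembrane protein gene, rose by 3.34 (SE 0.27, adjusted p = 0.00653). Csf2rb, the shared beta chain of the IL-3, IL-5 and GM-CSF receptors (3.11, SE 0.40), and its close copy Csf2rb2 (2.67, SE 0.32) rose together, and reads of the pair cannot be fully separated. Cmah, a sialic acid hydroxylase gene (1.99, SE 0.26), Fam110d (1.99, SE 0.26) and Acer2, an alkaline ceramidase gene (1.81, SE 0.28), were also among the 12 largest. Tmem252 was called in all 8 fits that leave out 1 library. Calls were lost without control 1 for Selp (adjusted p = 0.0526), without control 1 or 3 for Csf2rb2 and Fam110d, without control 1, 2 or 3 for Csf2rb, and without these or scMC38 2 for Cmah (up to 0.0865 in each of these 4). Acer2 kept its call only without scMC38 2 (up to 0.113 otherwise). Endothelial markers as a list did not pass (16 tested, 0 called, 1 lower when adjusted over the list alone, median -0.06, camera adjusted p = 0.86). The VEGF receptor gene Kdr stood at -1.13 (adjusted p = 0.0865) and the junction gene Cldn5 at 0.63 (adjusted p = 0.165).

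Of 37 extracellular matrix genes 5 were called, all lower, and 12 had a positive log2 fold change. The 5 were Col3a1, a fibrillar collagen (from 266 ± 83.4 to 68.4 ± 28.4 CPM, SD, n = 4; -1.96, SE 0.33, adjusted p = 0.0352), Col5a3 (-1.48, SE 0.19, adjusted p = 0.0201), Col6a2 (-1.41, SE 0.21, adjusted p = 0.0299), Col6a1 (-1.21, SE 0.23, adjusted p = 0.0485) and the collagen crosslinking enzyme gene Loxl2 (-1.16, SE 0.17, adjusted p = 0.0299). Adjusted over the list alone, 9 were lower and 0 higher. The list's median was -0.24 (camera adjusted p = 3.2e-07; adjusted p = 0.49 with an estimated correlation), -0.60 without scMC38 3, -0.15 without scMC38 4 and -1.03 without scMC38 1 and 3 together. Its level was not even across the tumour group: -0.93 and -1.06 in scMC38 2 and 4, -0.12 in scMC38 1 and 0.33 in scMC38 3. Mfap4, a microfibril-associated gene (-1.63, SE 0.30, adjusted p = 0.0479), was among the 12 largest falls. Col5a3 lost its call without control 1, 2 or 3 (adjusted p up to 0.0865) and Col6a2 without any 1 control or scMC38 2 (up to 0.0963). Col3a1, Col6a1, Loxl2 and Mfap4 kept theirs only without scMC38 1 (up to 0.102, 0.131, 0.0963 and 0.127 otherwise).

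Of the markers of stromal and nerve cells, Smoc2 alone was called. Smoc2, a matricellular protein gene, fell by 0.70 (SE 0.13, adjusted p = 0.0479) within 15 fibro-adipogenic progenitor markers (2 lower when adjusted over the list alone, median -0.33, camera adjusted p = 7.4e-06; adjusted p = 0.43 with an estimated correlation). No smooth muscle and pericyte marker was called (12 tested, 4 lower when adjusted over the list alone, median -0.46, camera adjusted p = 0.00016; adjusted p = 0.29 with an estimated correlation), with Myh11 at -0.75 (adjusted p = 0.0837) and Acta2 at -0.92 (adjusted p = 0.0865). Schwann and nerve markers (14 tested, 0 called, 7 lower when adjusted over the list alone, median -0.66, camera adjusted p = 2.4e-06; adjusted p = 0.43 with an estimated correlation) included the myelin gene Pmp22 (-0.63, adjusted p = 0.0794) and Gldn (-1.49, adjusted p = 0.0849). Tenocyte markers (10 tested, 0 called, 3 lower when adjusted over the list alone, median -0.66, camera adjusted p = 0.0031; adjusted p = 0.50 with an estimated correlation) included the cornea and tendon proteoglycan gene Kera (-2.08, adjusted p = 0.0568) and Tppp3 (-0.91, adjusted p = 0.0882). The tenocyte call was lost without scMC38 2 (adjusted p = 0.0628), and its median was -0.35 without control 3 and -1.77 without scMC38 1 and 3 together. Tenocyte levels were 0.41 and 0.34 in scMC38 1 and 3 and -2.15 and -1.21 in scMC38 2 and 4. The median of the progenitor list was -0.56 without scMC38 1 and 3. Smoc2 was called only without scMC38 3 when 1 library was left out (up to 0.129 otherwise). Adipocyte markers did not pass (15 tested, 0 called over all genes or over the list alone, median -0.08, mean -0.17, camera direction up, adjusted p = 0.57), with Plin4 at 0.70 (adjusted p = 0.112) and Pparg at -0.42 (adjusted p = 0.396). The adipocyte level of control 4 was 1.67, against -0.87 to -0.30 in the other controls, and without it the list was called higher (median 0.72, camera adjusted p = 0.000103).

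The largest falls by the fixed rule were not confined to matrix genes. Nr4a3, an activity-induced nuclear receptor gene (from 14.2 ± 4.43 to 2.37 ± 0.743 CPM, SD, n = 4; -2.59, SE 0.29, adjusted p = 0.0162), and Nrep, a neuronal regeneration related gene (from 111 ± 16.9 to 24.8 ± 5.54 CPM, SD, n = 4; -2.17, SE 0.17, adjusted p = 0.00653), led. The forkhead factor gene Foxo6 (-1.97, SE 0.24, adjusted p = 0.0162), the potassium channel subunit gene Kcng4 (-1.75, SE 0.28, adjusted p = 0.0334) and Tcim (-1.70, SE 0.28, adjusted p = 0.0341) followed. Further falls were those of Mdga1, which encodes a GPI-anchored surface protein (-1.55, SE 0.18, adjusted p = 0.0162), the scavenger receptor gene Ssc5d (-1.47, SE 0.23, adjusted p = 0.0310) and the angiopoietin-like gene Angptl1 (-1.43, SE 0.15, adjusted p = 0.0121). Nrep was called in all 8 fits that leave out 1 library. Nr4a3, Foxo6, Mdga1 and Angptl1 were called in all but that without control 1 (adjusted p = 0.0780, 0.0780, 0.0865 and 0.0526). Kcng4 was called only without scMC38 3, Ssc5d only without scMC38 1, and Tcim only without control 2 or control 4 (up to 0.101, 0.0963 and 0.0963 otherwise). Nr4a3 and Dusp1 were the calls, both lower, among 23 immediate early genes, of which 3 were higher and 5 lower when adjusted over the list alone (median -0.35, camera adjusted p = 0.046; adjusted p = 0.63 with an estimated correlation). That list lost its call without control 1, control 2, scMC38 1, scMC38 2 or scMC38 4 (adjusted p = 0.141, 0.259, 0.0585, 0.442 and 0.0892), and without control 1 and 2 together (median -0.03, adjusted p = 0.977). Its median was -0.12 without control 2, -0.61 without control 4 and -0.59 without scMC38 1 and 3 together. With the filter of at least 1 CPM the list was not called (median -0.07, adjusted p = 0.381).

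No gene of energy metabolism on the fixed lists was called, while several lists were lower by camera. Of 79 nuclear-encoded oxidative phosphorylation genes 78 had a negative log2 fold change (median -0.33, camera adjusted p = 1.8e-10; adjusted p = 0.54 with an estimated correlation), with Ndufc2 at -0.47 (adjusted p = 0.117) and Ndufc1 at -0.36 (adjusted p = 0.134). All 13 mitochondrially encoded mRNAs were negative (median -0.49, camera adjusted p = 0.00011; adjusted p = 0.50 with an estimated correlation), with mt-Nd4l at -0.53 (adjusted p = 0.234) and mt-Nd1 at -0.53 (adjusted p = 0.253). Of 20 tricarboxylic acid cycle genes 19 were negative (median -0.27, camera adjusted p = 0.0014; adjusted p = 0.62 with an estimated correlation), with Idh3a at -0.57 (adjusted p = 0.113) and Dlat at -0.39 (adjusted p = 0.239). That call was lost without control 2 (adjusted p = 0.102). Adjusted over each list alone, none of these genes passed. Without control 2 alone the 3 medians were -0.17, -0.27 and -0.14. Without control 1 and 2, the libraries with the most mitochondrially encoded counts, the 3 medians were -0.03, -0.03 and -0.02, and none of the 3 lists passed (adjusted p = 0.630, 0.436 and 0.937). Without scMC38 1 and 3, camera still called the nuclear-encoded list lower (median -0.23, adjusted p = 0.00187). The mitochondrially encoded mRNAs (median -0.35, adjusted p = 0.111) and the cycle genes (median -0.13, adjusted p = 0.432) did not pass in that fit.

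Glycolysis and glycogen genes (27 tested, 0 called, 1 lower when adjusted over the list alone, median -0.10, camera adjusted p = 0.049; adjusted p = 0.62 with an estimated correlation) included Pgam2 (-0.70, adjusted p = 0.0713) and Tpi1 (-0.58, adjusted p = 0.0971). The call was lost without control 3, control 4 or scMC38 3 (adjusted p = 0.0753, 0.122 and 0.496), and without scMC38 1 and 3 together (median -0.04, adjusted p = 0.922). The median was -0.06 without scMC38 3, -0.17 without scMC38 4 and -0.22 without control 1 and 2 together. The filter of at least 1 CPM also ended the call (adjusted p = 0.0590), and with total counts the median was 0.0019. Fatty acid oxidation and uptake did not pass (32 tested, 0 called over all genes or over the list alone, median -0.11, camera direction up, adjusted p = 0.87), with Ppard at 0.31 (adjusted p = 0.158) and Ucp2 with an adjusted p of 0.186 for a higher value. The list was called higher without control 2 (median 0.17, adjusted p = 0.00633) and without control 1 and 2 together (median 0.40, adjusted p = 4.12e-09). Mitochondrial biogenesis and dynamics genes did not pass either (24 tested, 0 called, 2 higher and 3 lower when adjusted over the list alone, median -0.14, camera adjusted p = 0.13), with Dnm1l at -0.34 (adjusted p = 0.0875) and Fundc1 at -0.33 (adjusted p = 0.0894). They were called lower without control 4 (adjusted p = 0.00491) or scMC38 4 (adjusted p = 0.0229). The same held for lipid synthesis (25 tested, 0 called over all genes or over the list alone, median -0.26, camera adjusted p = 0.089), with Acacb at 0.43 (adjusted p = 0.0849) and Lpin1 at 0.65 (adjusted p = 0.0964). The lipid list was called lower without control 1, control 2 or scMC38 2 (adjusted p = 0.0342, 0.0488 and 0.00346), and without control 1 and 2 together (adjusted p = 0.00918). Pdk4, which restrains glucose oxidation, stood at 0.36 (adjusted p = 0.496) and the mitochondrial coactivator gene Ppargc1a at -0.55 (adjusted p = 0.234).

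**Figure D3:**
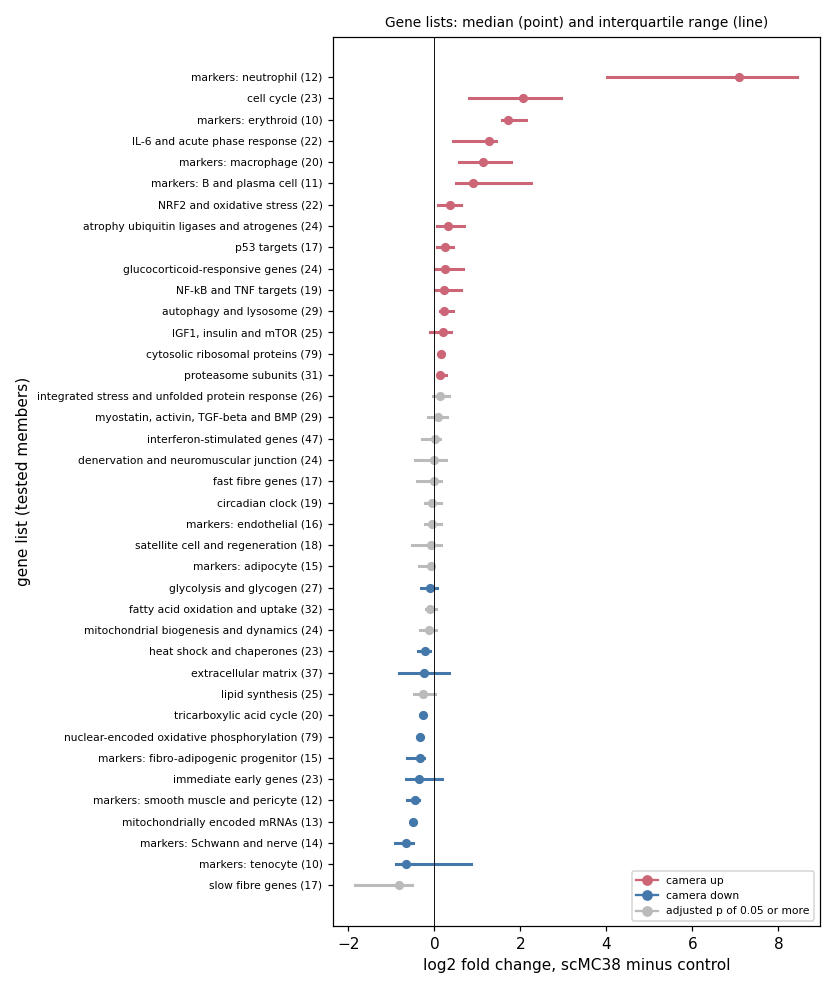
Median log2 fold change (point, x axis) and interquartile range (line) over the tested members of 39 gene lists (y axis, number of tested members in brackets). Red marks the 15 lists higher and blue the 11 lower by camera at an adjusted p under 0.05 with the preset correlation, grey the rest, and none of the 26 calls held with an estimated correlation. The neutrophil list stands farthest from 0, at 7.09.

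None of the 4 myosin isoforms named passed. Myh4, the fast IIb myosin and the most abundant of the 4 isoforms named, was at 32140 ± 11800 CPM in controls and 37880 ± 9020 CPM in scMC38 (SD, n = 4; log2 fold change 0.24, SE 0.32, not called by edgeR). Myh1 (-0.21, adjusted p = 0.879), Myh2 (-1.65, adjusted p = 0.462) and the slow myosin gene Myh7 (-1.35, adjusted p = 0.719) did not pass. Myh7 ranged from 0.0546 to 185 CPM over the 4 controls. Neither the fast fibre list (17 tested, 0 called over all genes or over the list alone, median -0.01, camera adjusted p = 0.39) nor the slow fibre list (17 tested, 0 called over all genes or over the list alone, median -0.83, camera adjusted p = 0.19) passed. Casq1 (-0.72, adjusted p = 0.124) and Myl1 (-0.65, adjusted p = 0.147) had the smallest p of the former, and Sln (0.85, adjusted p = 0.349) and Myl3 (-3.06, adjusted p = 0.350) had the smallest p of the latter. Camera called the slow fibre list lower with total counts (median -0.65, adjusted p = 0.0275) and without control 4 (median -1.24, adjusted p = 0.000484), while its median was -0.035 without control 2. It called the fast fibre list lower without control 1 and 2 together (median -0.11, adjusted p = 0.00969).

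The remaining muscle programmes did not pass camera. Denervation and neuromuscular junction genes (24 tested, Gadd45a called, 1 higher when adjusted over the list alone) had a median of -0.00028 with camera direction up (adjusted p = 0.99). Satellite cell and regeneration genes (18 tested, 0 called, 2 higher and 3 lower when adjusted over the list alone, median -0.08, camera adjusted p = 0.19) included Myf6 (0.53, adjusted p = 0.0682) and Chodl (-0.70, adjusted p = 0.0845). For this list fry gave an adjusted p of 0.033 for a fall. Myostatin, activin, TGF-beta and BMP genes (29 tested, 0 called over all genes or over the list alone, median 0.07, camera direction down, adjusted p = 0.99) included Bmp6 (-1.13, adjusted p = 0.0757) and Fstl1 (-0.74, adjusted p = 0.109). Circadian clock genes (19 tested, 0 called, 2 higher and 1 lower when adjusted over the list alone, median -0.05, camera direction up, adjusted p = 0.89) included Bhlhe41 (-0.69, adjusted p = 0.0682).

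**Figure D4:**
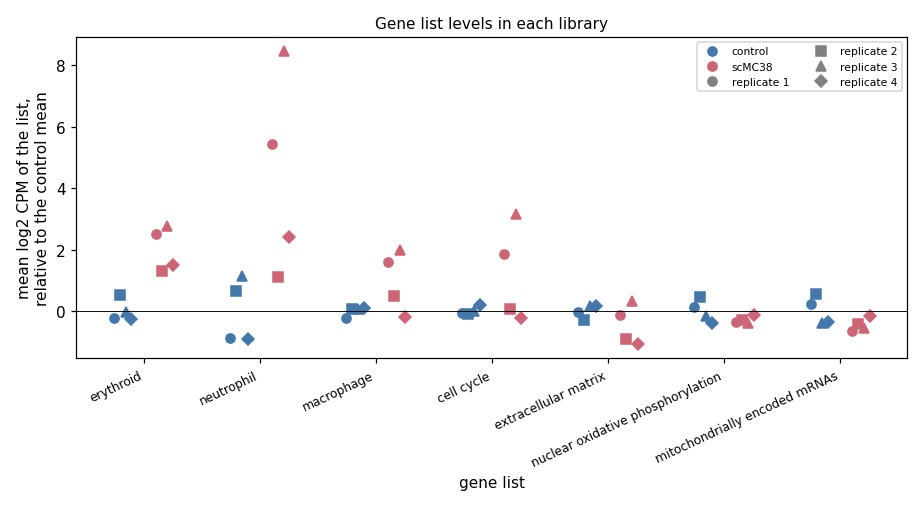
Mean log2 CPM of 7 gene lists (x axis) in each library, relative to the control mean (y axis), 1 symbol per library, blue for control and red for scMC38, with marker shapes for the replicate number. The erythroid level is above every control in all 4 scMC38 libraries, neutrophil and cell cycle levels are highest in scMC38 3 and 1 (8.45 and 5.44, 3.16 and 1.84), and control 2 has the highest levels of both oxidative phosphorylation lists (0.46 and 0.54).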

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

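The tests below were chosen after the result was seen, except that of the bone cell genes and that of the platelet genes.

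Within each group of 4 libraries, a value was singled out where its gap to the nearest other library, as a share of the group's range, passed Dixon's 95% limit. Chance does this in about 1 in 20 groups, and 15 of the 318 groups of values tested were singled out where chance gives 15.9. The number of them is thus no more than noise would give, though many of these values vary together. Libraries that stand apart as a pair hide each other from this rule, so it says nothing about scMC38 1 and 3 as a pair. Among list levels these were the IGF1, insulin and mTOR list in scMC38 3 (gap share 0.881, level 0.0056 against 0.21 to 0.23), the integrated stress list in scMC38 3 (0.832) and the macrophage list in control 1 (0.844). Among genes, control 2 was apart for Hbb-bt (0.847) and Foxo6 (0.884), control 3 for Trim63 (0.867) and Socs3 (0.884), and control 4 for Ppp1r15a (0.886), Gpx3 (0.834) and Krt19 (0.889). In the tumour group, scMC38 1 was apart for Foxo6 (0.844), Kdr (0.851) and Sele (0.858), scMC38 3 for Tpi1 (0.956), and scMC38 4 for Ppp1r15a (0.880).

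Neutrophil, cell cycle and band 3 genes were high in scMC38 1 and 3, the libraries that the first principal component sets apart. More blood of unchanged composition is argued against as the whole cause, since the median log2 ratio of these libraries over scMC38 2 and 4 was 4.43 larger for neutrophil genes (5.23) than for haemoglobin genes (0.80). The prediction for bone or bone marrow tissue in these samples, set before the values of the bone cell genes were seen, was met. Of genes of bone-forming and bone-resorbing cells, 13 of 13 were higher in scMC38 1 and 3 than in scMC38 2 and 4 (median log2 ratio 3.12). Among them was Ibsp (40.6 and 137 CPM against 0 and 1.4 CPM, and 0 to 0.06 CPM in controls). Genes of marrow progenitors had a median of 6.38, with Mpo at 18.3 and 174 CPM, against 0 to 0.1 CPM in controls. Such tissue would give these values, and how it came into the samples stays open. The bone genes were weaker in scMC38 1 than in scMC38 3 (median 1.69 and 4.73 over the controls, 11 and 13 of 13 positive). Marrow cells alone are argued against in scMC38 3, where all 13 bone genes lay above the controls, and less clearly in scMC38 1. A piece of bone taken along at dissection could give these values, and bone changes caused by the tumour only if bone tissue was in the sample. No test here separates these origins.

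Haemoglobin genes were higher in all 4 scMC38 libraries than in any control, and marrow in scMC38 1 and 3 is argued against as the whole cause, since without these libraries the median log2 fold change of the 4 haemoglobin genes was still 1.27 (largest SE 0.314). It was 1.74, 1.67, 1.56 and 1.91 with all libraries, and the calls ended with 2 libraries in the group (adjusted p between 0.0775 and 0.106 by edgeR), where the fold is smaller and fewer libraries are left, so the higher level there is a value and not a call. More blood in the muscle cannot be told apart from a change in the blood itself. In scMC38 2 and 4 over the controls the median haemoglobin log2 ratio exceeded that of 7 platelet genes by 1.07. This was hardly more than the bound of 1 set in advance. By that bound alone the value went against more blood of unchanged composition. An allowance for the spread was added after the value was seen, and with it the test does not decide. The platelet genes ran from -0.61 to 1.60 and most lie under 1 CPM. In the same comparison 16 of 16 neutrophil genes were higher (median 1.64), close to the haemoglobin ratio (1.32). The tested neutrophil genes vary together, with an estimated correlation of 0.92, so they are not separate observations. The neutrophil list level was 1.1 in scMC38 2, below control 3 (1.14), and 2.40 in scMC38 4. Anaemia with release of young red cells, which carry more haemoglobin mRNA, is a biological possibility, a hypothesis that was not tested here.

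Oxidative phosphorylation mRNAs were lower in scMC38 as a list. Without control 1 and 2 the median log2 fold change was -0.0271, but these libraries have the highest levels of the list (0.12 and 0.46), so leaving them out had to shrink it and decides nothing about the cause. Over the 8 libraries the level of the list followed that of 6 genes chosen to stand for oxidative fibres (Pearson r = 0.735, exact permutation p = 0.0417). They were Myh2, Myh1, Mybpc1, Ankrd2, Myoz2 and Csrp3. Myh1 and Myh2 stand on the fixed fast fibre list and the others on the slow fibre list. Without control 4 and control 2 r was 0.691. This relation is consistent with a different share of oxidative fibres in the piece of muscle sampled, which is a hypothesis. A loss of mitochondrial transcripts caused by the tumour stays open, as no test here excludes it.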

How the results depend on the processing

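Leaving out scMC38 1 and 3 together, and control 1 and 2 together, was chosen after seeing the data; the other alternatives were planned. All 170 called genes kept their direction in each setting that tested them. This says little about stability: in each of them all scMC38 libraries lay on 1 side of all controls, so leaving libraries out could hardly reverse the sign. The counts of higher and lower genes stayed within 1.5 times of 104 and 66 with DESeq2 size factors, without mitochondrially encoded genes, with limma-voom and with the filter of at least 1 CPM. They moved further with total counts (216 higher), DESeq2 (926 and 585, all 170 among them), voom quality weights (354 and 289), no filter (69 higher) and an adjusted p under 0.10 (386 and 345). On simulated counts DESeq2 made 41 false calls of 178, and limma-voom with quality weights 0 of 100. The simulated genes varied independently and no simulated library was set apart, unlike scMC38 1 and 3 here. These figures thus give no error rate for the calls on the real libraries, least of all for the quality weights. Leaving out 1 library gave 1 to 59 higher and 1 to 52 lower genes, leaving out scMC38 1 and 3 gave 25 and 39, and leaving out control 1 and 2 gave 0 and 0 by edgeR (1605 at an unadjusted p under 0.05). Fewer libraries lower the power of each of these fits. Camera called 13 to 15 lists higher and 10 to 12 lower when leaving out 1 library, 0 and 0 with an estimated correlation, and 6 and 1 were called by fry.

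With the replicate number as a block, edgeR called 0 genes higher and 1 lower, with 2004 at an unadjusted p under 0.05. The labels do not say that the numbers pair the samples. The deviations of same-numbered libraries correlated at -0.17, -0.32, -0.068 and -0.34, so no pairing was seen. A shared effect smaller than the differences between mice is not excluded by this.

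The direction reversed for 14 lists and 10 genes in at least 1 setting, 4 of the lists and 0 of the genes being called with all libraries. That 0 nearly follows from the separation of every called gene between the groups. A list's direction is that of its test, which can differ in sign from the median given. With total counts: fatty acid oxidation 0.0051, denervation 0.098, adipocyte -0.033. With the block: myostatin and TGF-beta 0.073, Myh1 0.095, Col1a1 -0.38. With limma-voom: Myh1 0.26, Col1a1 -0.28, and with quality weights Col1a1 -0.83. Without scMC38 1 and 3: mitochondrial biogenesis -0.010, fast fibre 0.18, cell cycle -0.010, B and plasma cell -0.059, Mki67 -0.068, Col1a1 -2.11, Sln -0.15, Il7r -0.88, Cd4 -0.38. Without control 1 and 2: tricarboxylic acid cycle -0.023, mitochondrial biogenesis 0.054, slow fibre -0.21, denervation -0.049, circadian -0.12, immediate early -0.030, adipocyte -0.75, endothelial 0.22, Mstn -0.16, Myh1 1.06, Myh2 0.28, Myh4 -0.12. Leaving out 1 library: denervation -0.098 to 0.091, myostatin and TGF-beta -0.019 to 0.13, circadian -0.11 to 0.036, adipocyte -0.43 to 0.72, slow fibre -1.24 to -0.035, endothelial -0.18 to 0.083, fatty acid oxidation -0.25 to 0.17, fast fibre -0.074 to 0.080, interferon -0.17 to 0.085, Myh1 -0.57 to 0.31, Fbxo30 -0.040 to 0.094, Col1a1 -1.27 to 2.23, Cd4 -0.18 to 0.80. The cause was not tested.

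Lists that passed camera only in some settings are given with their list in the report. With total counts these called lists kept their call with medians moved by over 1.5 times: proteasome 0.24, NF-kB 0.35, nuclear oxidative phosphorylation -0.22, tricarboxylic acid cycle -0.17, matrix -0.13, IGF1 0.33, ribosomal 0.27, heat shock -0.11, immediate early -0.22, p53 0.37 and progenitor -0.22. With the block the medians of the matrix (-0.38), immediate early (-0.22) and cell cycle (1.17) lists moved as far, and the glycolysis list was not called (adjusted p = 0.0948). Depth limits genes under about 1 CPM, such as Krt19, Cdh1 and Sele in controls.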

Other observations

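The venular endothelial list and Col1a1 were chosen after their values were seen, and so was the test on the number of genes called in other splits; that on the number of lists was not.

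Of 10 genes of venular and activated endothelium, put together around genes already called, 5 were called by edgeR, all higher: Sele, E-selectin (log2 fold change 4.76, SE 0.64, adjusted p = 0.0226), Selp (3.26, SE 0.30, adjusted p = 0.00731), Ackr1, the chemokine receptor of venules (1.77, SE 0.23, adjusted p = 0.0201), Lrg1 (1.76, SE 0.22, adjusted p = 0.0167) and Plvap, of fenestrated and venular endothelium (1.00, SE 0.16, adjusted p = 0.0324). The other 5 were not called, and as the 10 were picked in this way no test of them as a group was made. The fixed endothelial list did not pass (median -0.06, camera adjusted p = 0.86), and which cells the called mRNAs came from was not tested. Without scMC38 1 and 3 Sele stayed at 4.96 (adjusted p = 0.0403), Selp at 3.16 (adjusted p = 0.0350) and Lrg1 at 1.41 (adjusted p = 0.0295), while Ackr1 (1.73, adjusted p = 0.0559) and Plvap (0.91, adjusted p = 0.0597) missed the threshold. Without control 1 and 2 none of the 5 was called by edgeR (Selp 3.05, adjusted p = 0.138). With 1 library left out, calls were lost without control 1 for Selp (adjusted p = 0.0526), without control 1, 2 or 3 for Ackr1 and Lrg1 (up to 0.0865), and without these or scMC38 2 for Sele (up to 0.0833). Plvap kept its call only without control 4 or scMC38 3 (up to 0.107 otherwise). Sele lies at or below 1.17 CPM in every library.

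Col1a1, type I collagen, which bone and connective tissue share, stood at 2210 CPM in scMC38 3 and 134 CPM in scMC38 1, against 46.6 and 30.9 CPM in scMC38 2 and 4 and 114 to 234 CPM in controls. Its log2 fold change was 1.84 (SE 1.26, adjusted p = 0.429 by edgeR) with all libraries and -2.11 (adjusted p = 0.0597) without scMC38 1 and 3. The matrix list fell further without them (median -1.03 against -0.24, camera adjusted p = 7.96e-34).

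The number of calls was compared with all 35 ways to divide the 8 libraries into 4 and 4. Only the real split called any gene (170, highest other 0, 1 of 35 splits). This argues against chance for the gene count, at the smallest share the design allows, and the count itself falls to 2 without control 1 and to 0 by edgeR without control 1 and 2 (1605 genes at an unadjusted p under 0.05). Chance cannot be excluded for the list count: 2 of the 35 splits called at least 26 lists, the real one and the one that sets control 1, control 2, scMC38 1 and scMC38 3 against the rest (highest other 26), and no split called fewer than 10. With the preset correlation, many list calls could thus come from any grouping of these libraries.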
